A study of Mus musculus with 6 samples.

How the data were processed

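Single-nucleus RNA sequencing (10x Genomics) was deposited for 6 libraries of sorted colon nuclei: Control (n = 2), Stress (n = 3; 7 days of daily restraint) and Dexamethasone (n = 1; 7 days of injections). Per the file headers, the authors made the counts with Cell Ranger 4.0.0 for the Control and Stress libraries and 5.0.1 for the Dexamethasone library, while the submitters' notes name version 5 and the mm10 build; the version therefore changes together with the Dexamethasone group. The values are deposited counts of unique molecular identifiers (UMIs) per gene and barcode, whole numbers. The remaining deposited files are other values, the names of genes and barcodes. Whether intronic reads were counted is not stated. The files hold 31053 genes, of which 30934 IDs were found in GENCODE M21 (GRCm38); 35 symbols are used by more than 1 ID, and those genes were kept apart by ID.

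The group of each library came from the labels, which were read before the data were examined, as were the comparisons, the tests, the rule for naming genes and most alternatives. The labels state no shared batch, pairing or number of animals per library.

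Nuclei with at least 300 genes and at most 5% mitochondrially encoded UMIs were kept (3461 of 11040 barcodes), and scrublet through scanpy, run on each library, removed 44 doublets (1.271%), leaving 3417. Counts were scaled to 10000 per nucleus and log-transformed. The 2000 most variable genes (library as batch key; mitochondrially encoded, ribosomal, sex-linked, glucocorticoid receptor target and immediate early genes left out) gave 30 principal components, a graph of 15 neighbours and Leiden clusters at resolution 1.0. Clusters were named from 18 marker lists by the mean log2 fold of the markers (CPM with 10 added) over the other nuclei, with a threshold of 0.5 for neurons and glia and 1.5 for other classes and at least 3 markers each found in at least 10% of the nuclei. These thresholds were set after seeing the clusters. A cluster without leading markers whose median UMIs were under 1/3 of its own library's stayed unnamed.

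UMIs were summed per library over glia-like and neuron-like nuclei. Sums for glia-like nuclei were 468777 and 438267 in Control 1 and 2, 310277, 477779 and 873097 in Stress 1, 2 and 3, and 673602 in Dexamethasone; for neuron-like nuclei they were 675354, 355971, 247882, 1246875, 1378163 and 606523 in the same order. Genes were filtered by edgeR's filterByExpr, normalized by TMM and tested with edgeR's quasi-likelihood F-test, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Stress against Control used those 5 libraries. Dexamethasone against Control used all 6, so its single library is assumed to vary like the others. The stress effects of the 2 classes were compared in 1 model with the library as a block.

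The 18 gene lists (371 genes) were tested with limma's camera at a correlation of 0.01 where at least 4 members were tested, with an estimated correlation and fry as alternatives; each list was also adjusted alone. Some lists had an estimated correlation below 0.01, so correlated genes do not account for their higher p in that alternative. Cholinergic, nitrergic and neuropeptide lists had fewer than 4 tested genes in stress glia-like nuclei. Shares of nuclei were compared by exact permutation of the libraries. The agreement of the 2 treatments was set against 20 simulations of unchanged groups sharing the Control libraries. A test added after seeing the data gave each treatment a different Control library, in a fit with the 2 Control libraries as separate groups. CPM of genes are UMIs scaled to the TMM-adjusted total of the tested genes, and CPM of marker sums are scaled to all UMIs of the class. Folds against a group with 0 UMIs use a floor of 3 counts over the group, and genes with 1 to 3 UMIs carry exact 95% counting intervals.

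Genes were named by rule: a fixed set for each class; up to 8 rising and 8 falling genes of largest log2 fold change among those passing, with an average log2 CPM of at least 4 and no overlap of libraries; and up to 10 passing list members. Where fewer than 5 passed, the 5 genes of smallest p in each direction were named. Some results of this rule are not reported here. Genes named as examples of a list, of the difference between treatments or of the difference between classes were chosen after their values were seen.

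Alternatives were DESeq2's size factors and Wald test, no filter on low counts, counts thinned to equal totals, a stricter filter of nuclei (at least 500 genes, at most 2% mitochondrially encoded), doublets kept, sex-linked genes left out, other clustering resolutions, replicate number as a block, and each library left out. Added after seeing the data were no mitochondrial filter, leaving out Control 1 and Stress 1 (the libraries of fewest UMIs per nucleus), smooth muscle-like cluster 5 without cluster 18, epithelium-like cluster 0 alone, and the comparison of Dexamethasone with Stress. The procedure was tested on simulated data with 200 changed genes in each of 5 simulations; the false share of calls was 6.21% for stress and 5.89% for dexamethasone in glia-like nuclei, and 8.01% and 10.1% in neuron-like nuclei.

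Software was Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, igraph 0.11.9, leidenalg 0.10.2, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.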

Results

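Single-nucleus RNA was counted in 6 libraries of nuclei sorted from the colon of C57BL/6J mice, a common laboratory strain, on a DNA stain and a nuclear tag (INTACT) meant to mark the enteric nervous system, the network of neurons and glia in the gut wall. There were 2 Control libraries, 3 Stress libraries from mice restrained daily for 7 days, and 1 Dexamethasone library from mice injected for 7 days with dexamethasone, a synthetic glucocorticoid. The series asks how enteric neurons and glia respond to psychological stress and to glucocorticoid signalling. The labels do not say that libraries of a group came from separate animals, so p-values measure the spread between these libraries, whether biological or technical.

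The files held 11040 barcodes and 58954323 UMIs (unique transcript counts) over 31053 genes. Totals were 6938731 and 14838057 UMIs in Control 1 and 2, 6057994, 13155051 and 9183093 in Stress 1, 2 and 3, and 8781397 in the Dexamethasone library. The median share of mitochondrially encoded UMIs per barcode was 8.80% and 19.8% in the Control libraries, 13.4%, 10.9% and 4.44% in the Stress libraries and 5.98% in the Dexamethasone library. Filtering kept unlike shares of the barcodes: 36.0% and 14.8% in Control 1 and 2, 30.3%, 32.2% and 52.6% in Stress 1, 2 and 3, and 43.3% in Dexamethasone. In all, 3417 nuclei remained, 30.951% of the barcodes. Their median depth was 1803.5 and 2109 UMIs per nucleus in Control, 1625, 3059.5 and 3480 in Stress, and 3810 in Dexamethasone.

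The nuclei formed 22 clusters. Neuron-like nuclei, led by genes such as Penk, Vip, Nos1 and Nmu, numbered 158 and 62 in Control 1 and 2, 34, 100 and 104 in Stress 1, 2 and 3, and 70 in Dexamethasone. Glia-like nuclei numbered 203 and 138 in Control, 124, 118 and 184 in Stress, and 114 in Dexamethasone. The other named clusters were epithelium-like, smooth muscle-like, fibroblast-like, lymphatic and vascular endothelium-like, macrophage-like and cycling cell-like, although the sort was meant to leave those cells behind. Epithelium-like clusters 0 and 15, glia-like cluster 10 and smooth muscle-like cluster 18 (84 nuclei) reached the score threshold with 0 of their own markers among their 10 leading genes. Those of cluster 18 held 1 marker of another class, so its name is uncertain. Clusters 4, 13, 17 and 20, with 284, 210, 23 and 117 nuclei, stayed unnamed. They held 16.4% and 28.6% of the nuclei in Control 1 and 2, 17.8%, 16.4% and 20.9% in Stress 1, 2 and 3, and 11.7% in Dexamethasone. The score thresholds for naming were set after seeing the clusters.

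Glia-like nuclei fell into clusters 7, 9 and 10, which held different shares of them in each group. Cluster 9, led by Frzb, Sox10 and Col11a1, held 118 and 90 of the Control nuclei, 71, 23 and 30 of the Stress nuclei and 20 of the Dexamethasone nuclei. Cluster 10, led by Rnf122, Nr4a2, Arih1, Nr4a3, Crem and Eftud2, of which Nr4a2, Nr4a3 and Crem are activity- or stress-induced genes, held 51 and 28 of the Control nuclei, 34, 67 and 119 of the Stress nuclei and 82 of the Dexamethasone nuclei. Cluster 7, led by Col28a1, Kcna1 and Scn7a, held 34, 20, 19, 28, 35 and 12 nuclei in the same order of libraries. Glial comparisons are over the 3 clusters together unless a cluster is named.

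In glia-like nuclei, stress went with higher interferon-response genes and with a changed set of circadian clock genes. Irgm1, an interferon-induced GTPase, rose 12.6-fold, from 5.97 ± 1.95 CPM (UMIs scaled to the TMM-adjusted total of the tested genes; SD, n = 2) in Control to 76.9 ± 13.6 (SD, n = 3) in Stress. Irgm1 had 5 UMIs over both Control libraries and 127 in Stress, a ratio of 13.9 (95% counting interval 5.79 to 43.4). Likewise, Iigp1, another of that family, went from 3 UMIs over both Control libraries to 255 in Stress, a ratio of 46.4 (95% counting interval 15.7 to 227). Arntl, which encodes the core clock activator BMAL1, went from 118 ± 33.9 CPM (SD, n = 2) to 13.9 ± 4.88 (SD, n = 3), while Tef, a clock output factor, rose from 49.6 ± 7.81 (SD, n = 2) to 178 ± 14.7 (SD, n = 3). Atf3, a stress-induced transcription factor, went from 659 ± 17.1 (SD, n = 2) to 208 ± 58.3 CPM (SD, n = 3).

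The edgeR quasi-likelihood test called 137 of 6545 genes changed in stress glia-like nuclei after Benjamini-Hochberg adjustment: 100 higher and 37 lower. Within cluster 9 alone it called 12 of 3739 genes (4 higher, 8 lower). Within cluster 10 alone it called 93 of 3192 (70 higher, 23 lower). Single clusters hold fewer UMIs, and cluster shares differed between the groups, so those shares can enter the calls over all glia-like nuclei. Log2 fold changes (± SE) were 3.66 ± 0.46 for Irgm1 (adjusted p = 9.62e-04), -3.06 ± 0.35 for Arntl (6.02e-04), 1.82 ± 0.25 for Tef (0.00200) and -1.65 ± 0.22 for Atf3 (0.00162). Iigp1, of few Control UMIs, had an adjusted p of 0.00162. Other large rises were Rrm1, a subunit of ribonucleotide reductase (3.16), Nop53 (3.55), Impdh2 (3.34), Isy1 (3.34) and Igsf10 (3.27). Of these, Nop53, Impdh2, Isy1 and Igsf10 had only 5, 4, 7 and 4 UMIs over both Control libraries. Ptgs2, the inducible cyclooxygenase, had 0 UMIs in Control and 76 in Stress, at least 13.8-fold higher with Control set to a floor of 3 counts over the group. Large falls were those of Ankfn1 (-3.75), Arntl, Pdk4 (-2.14), Cyp2c55 (-2.08), Zg16 (-2.06), Emp1 (-2.04) and Insig1, a brake on sterol synthesis (-1.93). Cyp2c55 and Zg16 are abundant colon epithelium genes. Epithelium markers had a median log2 fold change of -0.58 in these nuclei (camera adjusted p = 0.0668), and they summed to 525 and 929 CPM (of all UMIs of these nuclei, as in later sums of markers) in Control against 519, 816 and 362 in Stress.

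Of the genes named in advance, the immediate early gene Nr4a3 rose (2.63 ± 0.46, adjusted p = 0.00894 by edgeR), with 93 and 16 UMIs in Control and 148, 385 and 854 in Stress. It also leads cluster 10, although it was kept out of the genes used for clustering, and within cluster 10 its change was 2.22 (adjusted p = 0.00648). Within cluster 9 it was 1.12 (0.653), and the immediate early list there had a median of -1.11 (camera adjusted p = 4.02e-13; adjusted p = 0.151 with an estimated correlation). Fkbp5, a feedback regulator and standard target of the glucocorticoid receptor, was 3.95-fold higher without passing (1.98 ± 0.50, adjusted p = 0.0596), with 10 UMIs in Stress 1 against 63 and 113 in Stress 2 and 3. It passed without Control 1 (0.0312) and without Stress 1 (0.0133). The receptor gene Nr3c1 was at 0.06 ± 0.25 (adjusted p = 0.951), and the target genes Tsc22d3 and Per1 at 1.23 (0.321) and 1.13 (0.251). Per1 and Nr4a2 passed without Control 1 (0.00837 and 5.82e-05). Nr4a1 (0.18, adjusted p = 0.871), Nr4a2 (1.21, 0.293), the macrophage growth factor Csf1 (0.76, 0.681), Tgfb2 (0.47, 0.309), the glial identity factor Sox10 (0.38, 0.728) and the glial filament gene Gfap (-0.68, 0.101) did not pass.

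The interferon and antigen presentation list was the list that moved most: 10 of its 19 tested members rose, 0 fell and 9 did not pass, and 16 rose when adjusted over the list alone. All 19 members lay above 0 (median log2 fold change 1.62). Oasl2 (2.37), Ifit1 (3 UMIs in Control and 45 in Stress, ratio 8.19, 95% counting interval 2.63 to 41.2), Nlrc5, an activator of antigen presentation genes (1.56), and B2m, a light chain of MHC class I (1.52), were among those that rose. The list's camera adjusted p was 3.44e-27. It was adjusted p = 0.0399 with an estimated correlation and 0.0127 by fry's directional test. Macrophage markers moved with this list, summing to 10.7 and 13.7 CPM in Control and 29.0, 27.2 and 29.8 CPM in Stress. So did lymphatic endothelium markers, at 53.3 and 59.3 CPM in Control and 90.2, 103 and 149 CPM in Stress. Smooth muscle markers were at 149 and 185 CPM in Control and 190, 213 and 362 in Stress. Pericyte markers were at 44.8 and 43.4 against 61.2, 67.0 and 55.0, and glia markers themselves at 4021 and 3137 against 4915, 5687 and 5518. Fibroblast and epithelium markers overlapped between the groups.

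In the circadian clock list of 12 tested genes, Tef and Per2 (2.00, adjusted p = 0.0123 by edgeR) rose, Arntl fell and 9 did not pass, with 5 higher and 2 lower when adjusted over the list alone. The list went both ways, so its directional test was not passed (camera adjusted p = 0.127), and fry's mixed test, which ignores direction, gave an adjusted p of 0.00866. That test also passed for glucocorticoid receptor target genes (0.0326), reactive glia (0.0207), mature glia (0.0333), TGF-beta (0.0398), cytokine (0.0326) and interferon genes (0.00284). Of 21 immediate early genes, Nr4a3, Fosl2 (1.15) and Maff (1.62) rose, Atf3 and Klf6 (-1.35) fell and 16 did not pass, with 3 higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.362). Of 13 cytokine, chemokine and NF-kB genes Ptgs2 alone rose, with 2 higher when adjusted over the list alone (camera adjusted p = 0.00499; adjusted p = 0.556 with an estimated correlation). That list's call ended without Control 1 (adjusted p = 0.715) and without Stress 2 (0.0562).

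Of 22 glucocorticoid receptor target genes in stress glia-like nuclei, Irs2 (1.16) rose, Pdk4 fell and 20 did not pass, with 2 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.362). Ceruloplasmin (Cp, 2.38) was the member of 11 reactive glia genes that rose (1 higher and 1 lower adjusted over the list alone; 0.468). Of 17 TGF-beta genes 0 rose and 1 fell (1 higher and 1 lower adjusted over the list alone; 0.954). By edgeR, 0 genes passed among 16 mature enteric glia genes (camera adjusted p = 0.362), 5 corticosteroid receptor and metabolism genes (0.954), 9 synaptic genes (0.954), 12 immaturity genes (0.954), 14 heat shock genes (0.563), 17 axon guidance genes (0.563), 13 mitochondrially encoded genes (0.0882) and 4 sex-linked genes (0.362). Adjusted over the list alone, 1 mature glia gene was higher and 1 lower, 1 immaturity gene and 2 axon guidance genes were lower, 3 mitochondrially encoded genes and 1 sex-linked gene were higher, and 0 passed in the others; 858 of all genes had an unadjusted p under 0.05.

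**Figure D1:**
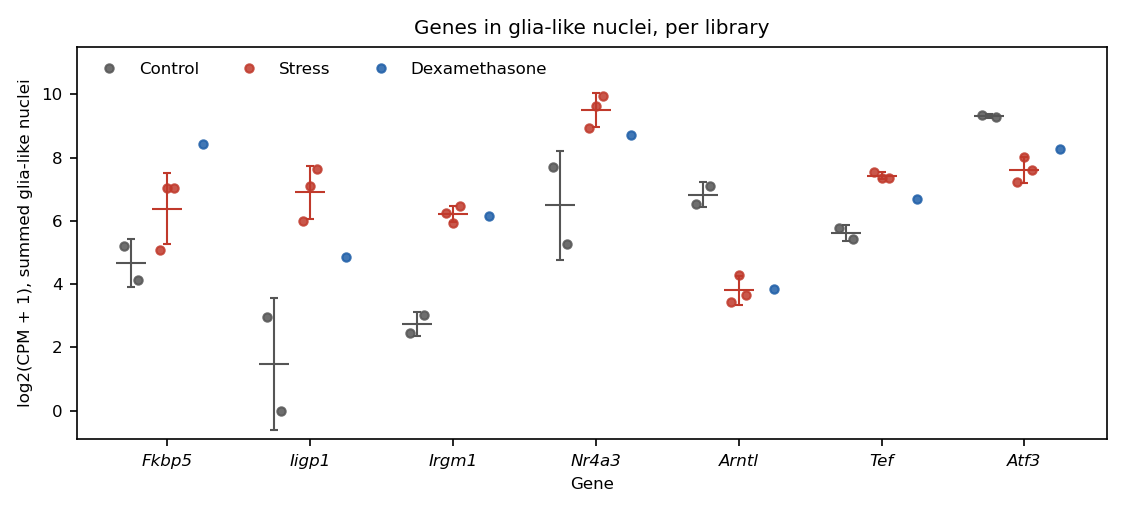
Levels of 7 genes in summed glia-like nuclei, as log2(CPM + 1) on the vertical axis. Points are libraries (Control, n = 2; Stress, n = 3; Dexamethasone, n = 1); horizontal marks and bars are the mean ± SD of the Control and Stress libraries. The Stress points of Iigp1, Irgm1, Nr4a3 and Tef lie above both Control points and those of Arntl and Atf3 below, while 1 Stress point of Fkbp5 lies between the Control points.

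The count of changed glial genes was 77 by DESeq2 (64 higher, 13 lower). It was 83 after thinning to equal totals, 32 with stricter filtering of nuclei, 84, 49 and 35 without Control 2, Stress 2 and Stress 3. In alternatives added after seeing the data it was 279 without the mitochondrial filter and 254 without Control 1 and Stress 1. Calls ended (adjusted p without each library by edgeR) for Nr4a3 without Stress 2 (0.0568) or Stress 3 (0.0725). They ended for Ptgs2 without Stress 3 (0.0654), Impdh2 without Stress 3 (0.0703), Igsf10 without Control 1, Stress 1, Stress 2 or Stress 3 (0.0560, 0.0527, 0.0979, 0.0852). They ended for Ankfn1 without Control 1, Control 2 or Stress 3 (0.142, 0.234, 0.0808). The same held for Pdk4 without Control 1, Control 2, Stress 2 or Stress 3 (0.138, 0.145, 0.0951, 0.0834), for Cyp2c55 without Control 1, Stress 2 or Stress 3 (0.140, 0.144, 0.163) and Zg16 without Control 2, Stress 1, Stress 2 or Stress 3 (0.462, 0.114, 0.0940, 0.245). The groups' libraries did not overlap in 29.5% of genes, where chance gives 20% for 2 against 3. On simulated counts the test recovered 30% of 2-fold and 82.4% of 4-fold changes in this comparison.

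In glia-like nuclei of the Dexamethasone library, glucocorticoid receptor target genes and inflammatory genes stood higher than in Control when the 3 clusters were summed. Fkbp5 rose 12.9-fold (log2 fold change 3.69 ± 0.49, adjusted p = 1.36e-04 by edgeR), from 16 and 7 UMIs in Control to 208. Tsc22d3, which encodes the glucocorticoid-induced protein GILZ, rose 4.71-fold (2.24 ± 0.54, adjusted p = 0.0167) and Per1 3.41-fold (1.77 ± 0.48, adjusted p = 0.0322). Nr3c1, the receptor gene itself, fell by 1.47 ± 0.41 on the log2 scale (adjusted p = 0.0374). Interleukin 6 (Il6) rose 27.8-fold (4.80 ± 0.55, adjusted p = 3.43e-05) and Nfkb1, an NF-kB subunit, 5.52-fold (2.46 ± 0.31, adjusted p = 6.86e-05). The single Dexamethasone library is assumed to vary like the Control and Stress libraries in each of these p-values.

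The edgeR quasi-likelihood test over all 6 libraries called 464 of 7679 genes, 416 higher and 48 lower. With 1 UMI each over both Control libraries, Adamts4 had 86 UMIs in Dexamethasone (ratio 116, 95% counting interval 20.2 to 4626.5), Slc10a6, a steroid sulfate transporter, 81 (109, 19.0 to 4361), Cnn1, a smooth muscle protein, 37 (49.8, 8.40 to 2020.4), Tchh 24 (32.3, 5.27 to 1329) and Hif3a 21 (28.3, 4.55 to 1169). Ptgs2 went from 0 to 15 UMIs, at least 6.73-fold higher, and Nup210l rose by a log2 fold change of 5.67. Cyp2c55 fell from 80 UMIs in Control to 1 in Dexamethasone (ratio 0.0168, interval 4.21e-04 to 0.0965). With 2 UMIs each in Dexamethasone, Mgst3 had 56 in Control (0.0481, 0.00568 to 0.182), Clca1 54 (0.0499, 0.00589 to 0.189), Adamts2 38 (0.0709, 0.00828 to 0.274) and Gabrg3 35 (0.0769, 0.00897 to 0.2995). Vgll3 (-3.11), Arntl (-3.09 ± 0.52, adjusted p = 9.74e-04) and Abcb1a (-3.08) fell. Nr4a3 was at 1.74 (adjusted p = 0.0537), Nr4a2 at 1.07 (0.331), Gfap at 0.73 (0.119), Tgfb2 at 0.35 (0.544), Sox10 at -0.29 (0.794), Nr4a1 at -0.08 (0.937) and Csf1 at 0.06 (0.979), all short of the threshold.

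Of 26 glucocorticoid receptor target genes in Dexamethasone glia-like nuclei, 11 rose, 0 fell and 15 did not pass (11 higher and 2 lower when adjusted over the list alone; camera adjusted p = 6.19e-07, but adjusted p = 0.148 with an estimated correlation). The metallothioneins Mt1 (2.21) and Mt2 (2.27) and the transcription factor Zbtb16 (2.37) were among them. Of 18 cytokine, chemokine and NF-kB genes 9 rose and 0 fell (10 higher adjusted over the list alone; 4.50e-10, adjusted p = 0.125 with an estimated correlation): besides Il6 and Nfkb1 these included Birc3 (2.97), Relb (1.83) and the neutrophil chemokines Cxcl1 (3.70) and Cxcl2 (0 UMIs in Control and 26 in Dexamethasone, at least 11.7-fold higher). The list's median log2 fold change of 1.70 was the same with Cxcl2 and Ptgs2 at their bounds. The rise was not seen in every cluster: within cluster 10 the cytokine list had a median of 1.95 (7 of 12 rose; camera adjusted p = 7.71e-06), and within cluster 9 it had -0.99 (0 of 5; 0.0936). The glucocorticoid receptor target list had 1.16 (7 of 20; 6.19e-04) and 0.12 (2 of 18; 6.08e-04). With an estimated correlation these were at 0.326, 0.325, 0.326 and 0.162. Cluster 10 held most of the Dexamethasone nuclei and fewer of the Control nuclei than cluster 9. Cluster shares can therefore enter both lists and the calls of single genes over all glia-like nuclei. Fkbp5 rose within cluster 9 (3.78, adjusted p = 2.31e-04) and within cluster 10 (3.96, 7.95e-05). Macrophage markers summed to 75.7 CPM in these nuclei, against 10.7 and 13.7 CPM in Control, and lymphatic endothelium markers to 223 CPM, against 53.3 and 59.3.

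Of 21 interferon and antigen presentation genes 6 rose and 0 fell in Dexamethasone glia-like nuclei, among them Gbp2 (3.72), Irgm1 (3.54) and Nlrc5 (2.20), with 9 higher when adjusted over the list alone (camera adjusted p = 6.19e-07; adjusted p = 0.125 with an estimated correlation). Of 11 reactive glia genes 4 rose, including the oncostatin M receptor Osmr (2.24), with 8 higher adjusted over the list alone (1.30e-04; adjusted p = 0.125 with an estimated correlation). Of 16 heat shock genes Bag3 (1.67) and Hsp90ab1 (1.07) rose, with 5 higher adjusted over the list alone (0.0230; adjusted p = 0.223 with an estimated correlation), and of 6 neuropeptide genes Tac1 (3.59) and Penk (2.79) rose, also with 2 higher adjusted over the list alone (0.0159; adjusted p = 0.611 with an estimated correlation). Both are also markers of excitatory motor neurons. Those markers summed to 316 CPM in these nuclei against 233 and 224 in Control, a sum that contains both genes and so decides nothing. Of the 5 tested, 2 lay above 0 and 3 below (median -0.15). Neuron markers summed to 287 CPM against 305 and 203 in Control. RNA of neurons was not tested further and is not excluded. In the clock list of 13 genes, Per1 and Nr1d2 (1.51) rose and Arntl fell (6 higher and 2 lower adjusted over the list alone; 0.0614), and of 21 immediate early genes Fosl2 (1.69) and Maff (1.63) rose and Jun (-1.34) fell (3 higher and 3 lower; 0.874).

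Smooth muscle markers stood out beside all of these groups: 7 of 8 rose in the Dexamethasone glia-like nuclei, with a median log2 fold change of 3.64 (camera adjusted p = 2.18e-10; adjusted p = 0.461 with an estimated correlation), and they summed to 149 and 185 CPM in Control, 190, 213 and 362 in Stress and 741 in Dexamethasone. Epithelium markers had a median of -1.36 (0.0108; adjusted p = 0.641 with an estimated correlation), and 0 of 10 passed singly. In the remaining lists, Nr3c1 fell among 5 corticosteroid receptor genes (camera adjusted p = 0.424), Dpysl3 rose among 13 immaturity genes (0.227), Smad1 rose among 19 TGF-beta genes (0.874) and Ddx3y rose among 4 sex-linked genes (0.176), each the same member when adjusted over its list alone. Of 12 synaptic genes 0 rose and 1 fell (1 lower adjusted over the list alone; 0.874). By edgeR, 0 passed, over all genes or adjusted over the list alone, among 16 mature glia (0.874), 4 nitrergic and VIP (0.874), 21 axon guidance (0.874) and 13 mitochondrially encoded genes (0.874), with 1429 genes in all at an unadjusted p under 0.05.

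**Figure D2:**
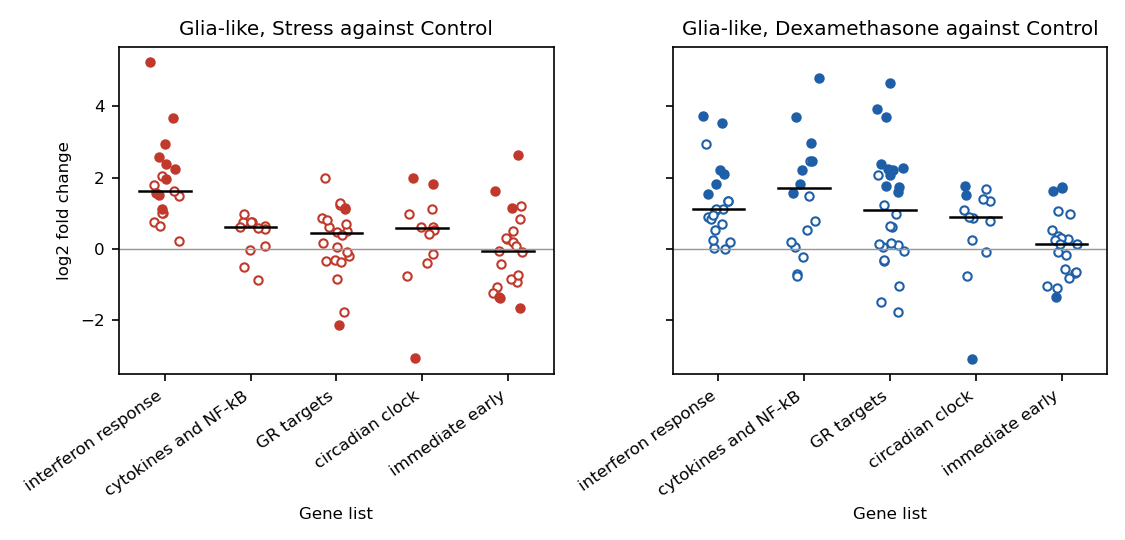
Log2 fold changes (vertical axis) of the tested members of 5 gene lists in glia-like nuclei, for Stress (left) and Dexamethasone (right) against Control. Each point is a gene, filled where its adjusted p passed the threshold and open where it did not; black lines are list medians, and genes with 0 UMIs in Control are counted in the median but not drawn. The interferon median is 1.62 in Stress and 1.12 in Dexamethasone, and the glucocorticoid receptor target median 0.43 and 1.09.

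DESeq2 called 196 of these genes (187 higher, 9 lower), and leaving out Control 2 gave 308. The calls of Nr3c1 ended without Control 1 (adjusted p = 0.0991) and Control 2 (0.0574). Those ending without Control 2 were Tsc22d3 (0.0994), Per1 (0.178), Mgst3 (0.197), Adamts2 (0.0944), and Abcb1a (0.148). Hif3a ended without Control 1, Control 2, Stress 2 or Stress 3 (0.0702, 0.164, 0.0574, 0.0609), and Tchh (0.0777), Clca1 (0.0559) and Gabrg3 (0.228) ended without Control 1. Nr4a3, in contrast, passed without Control 1 (2.24e-04) and without each of Stress 1 (0.0448), Stress 2 (0.0327) and Stress 3 (0.0359). In simulated counts for this comparison 10.8% of 2-fold and 53.0% of 4-fold changes were recovered.

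In neuron-like nuclei, no single gene passed adjustment in stress against control by edgeR. Of the genes of smallest p, Tubb5 and Tubb2a, tubulins abundant in growing neurons, were 2.74-fold and 2.40-fold higher (log2 fold change 1.45 ± 0.19 and 1.26 ± 0.18, adjusted p = 0.0858 for both by edgeR). The mitochondrial gene mt-Nd3 (1.27), the glycolytic enzyme gene Aldoa (1.36) and Tppp3 (1.16) followed, with adjusted p of 0.142, 0.142 and 0.159. Lower without passing were the drug transporter Abcb1a (-1.90, 0.0858), the epithelial genes Zg16 (-2.22) and Cyp2c55 (-2.57), the phosphodiesterase Pde11a (-1.38) and the receptor kinase Alk (-0.89), each of the last 4 at 0.166. Epithelium markers were lower as a list, with 8 of 8 below 0 and a median of -1.49 (camera adjusted p = 5.54e-10; adjusted p = 0.178 with an estimated correlation).

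The edgeR quasi-likelihood test called 0 of 8062 genes in this comparison, with 824 at an unadjusted p under 0.05 (522 higher and 302 lower). DESeq2 called 16 (10 higher, 6 lower), among them Tubb5 (adjusted p = 0.0105) and Tubb2a (0.0252). Chat, which makes acetylcholine, was at -0.16 ± 0.24 (adjusted p = 0.865), the choline transporter Slc5a7 at 0.39 ± 0.26 (0.641), Nos1, the neuronal nitric oxide synthase, at 0.31 ± 0.20 (0.621) and Vip, the relaxant neuropeptide, at 0.91 ± 0.33 (0.434). Nr3c1 (0.33, adjusted p = 0.789), Fkbp5 (0.10, 0.961) and Tgfb2 (-0.01, 0.999) did not pass. Tsc22d3, Per1 and Sox11, a factor of immature neurons, had too few UMIs to be tested. Slc18a3, the vesicular acetylcholine transporter, had 0 UMIs in every group. It lies inside Chat on the same strand of chromosome 14, from 32462438 to 32464850 within 32408203 to 32465989.

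As groups, 17 tested genes of neuronal immaturity and neurogenesis lay mostly above 0 in stress neuron-like nuclei (15 of 17, median 0.59), with 0 passing over all genes and 3 when adjusted over the list alone: Tubb2a, Tubb2b (1.51), and Hand2, a factor of enteric neuron development (1.17). The list's camera adjusted p was 6.48e-09, and it was adjusted p = 0.119 with an estimated correlation and 0.00257 by fry's directional test. All 13 mitochondrially encoded genes lay above 0 (10 higher adjusted over the list alone; 2.50e-16; adjusted p = 0.258 with an estimated correlation), in nuclei where they made up 1.26% and 1.21% of summed UMIs in Control and 2.30%, 2.41% and 1.79% in Stress. The mitochondrial call was lost and turned downward without the mitochondrial filter (adjusted p = 0.370). Heat shock genes (12 of 13 above 0, 5 higher adjusted over the list alone; 8.60e-07) and neuropeptides (10 of 12 above 0, with Penk at 1.39 and Tac1 at 0.93 higher adjusted over the list alone; 0.00752) were also higher, each at adjusted p = 0.305 with an estimated correlation. The neuropeptide call ended without Control 1 (adjusted p = 0.158) and without Stress 2 (0.111).

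For 7 interferon genes in stress neuron-like nuclei, 0 passed over all genes and 2 were higher when adjusted over the list alone (camera adjusted p = 0.0515). The other lists did not pass camera either: 9 cholinergic genes (0.175; Ache at 0.85 higher adjusted over the list alone), 24 synaptic genes (0.241; 4 higher), 10 clock genes (0.314; Nr1d2 at 1.32 higher, Arntl at -1.17 lower), 5 mature glia genes (0.621; Gfra2 lower), 10 glucocorticoid receptor target genes (0.314), 6 corticosteroid receptor genes (0.581), 14 immediate early genes (0.585), 4 cytokine genes (0.512), 8 nitrergic and VIP genes (0.175), 15 TGF-beta genes (0.241), 25 axon guidance genes (0.175) and 4 sex-linked genes (0.175). In those last 8 lists 0 genes passed when adjusted over the list alone.

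**Figure D3:**
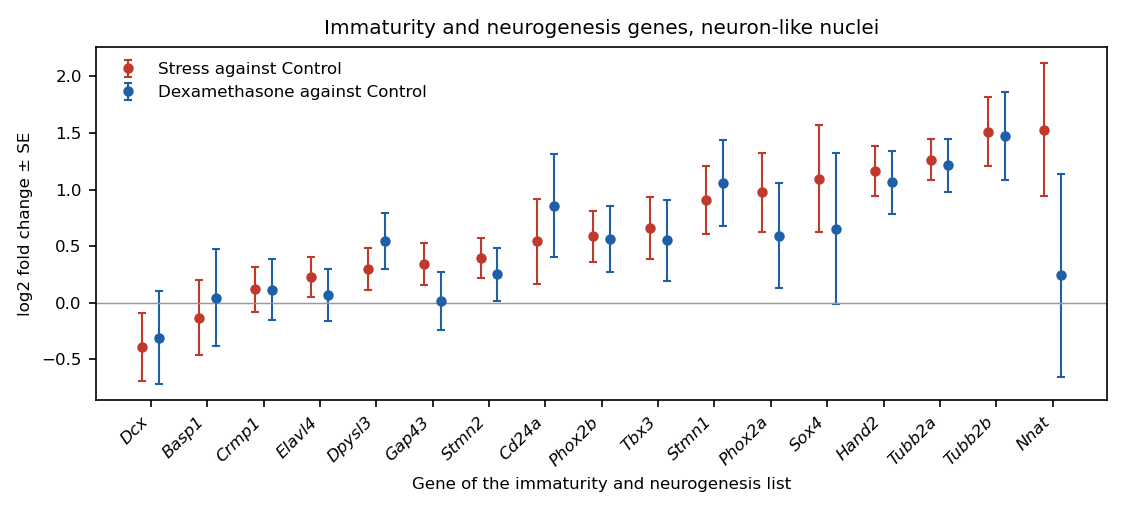
Log2 fold changes ± SE (vertical axis) of the 17 tested immaturity and neurogenesis genes in neuron-like nuclei, for Stress and Dexamethasone against Control. In Stress 15 of the 17 points lie above 0 and in Dexamethasone 16; no point passed adjustment over all genes.

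Without a filter on low counts the count of changed neuronal genes was 157, and without Control 1 or Control 2 it was 1. Leaving out both Control 1 and Stress 1, an alternative added after seeing the data, gave 75. The test recovered 33.6% of 2-fold and 83.0% of 4-fold changes in simulated neuron-like sums, with 8.01% of its calls false. Calls were therefore possible at this number of libraries where 200 genes changed. A response of fewer genes was not simulated, and its recovery is not known.

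In neuron-like nuclei of the Dexamethasone library, Vip was 4.92-fold higher (log2 fold change 2.30 ± 0.40, adjusted p = 0.0672 by edgeR), Penk, the enkephalin precursor, 3.62-fold (1.86 ± 0.29, 0.0672), Tgfb2 4.84-fold (2.27 ± 0.48, 0.114) and Fkbp5 3.67-fold (1.88 ± 0.42, 0.127), none passing with all libraries. Vip passed without Stress 1 (0.0284) and Stress 2 (0.00775), Penk without Stress 1 (0.0284), Stress 2 (0.0399) and Stress 3 (0.0275), and Tgfb2 without Stress 1 (0.0464). The unnamed transcript 4930555F03Rik (2.30), the stress-induced gene Trp53inp1 (2.67), the splicing factor Eftud2 (2.03), and the smooth muscle actin Acta2 (4.45) had the same adjusted p of 0.0672. Lower were Hdac9 (-1.50, 0.0672), Zfp804b (-1.63, 0.0717), Abcb1a (-2.31, 0.0728), Zg16 (-3.60, 0.0855) and Cyp2c55 (73 UMIs in Control, 2 in Dexamethasone, ratio 0.0466, 95% counting interval 0.00554 to 0.174; adjusted p = 0.116). Nr3c1 (-0.82, adjusted p = 0.652), Per1 (1.42, 0.530), Chat (0.02, 0.991), Slc5a7 (0.14, 0.922) and Nos1 (-0.19, 0.847) did not pass, and Tsc22d3, Sox11 and Slc18a3 were not tested. These p-values again assume that the single library varies like the others. Of its 70 neuron-like nuclei 41 lay in cluster 12, a sensory-like cluster led by Nmu with a median of 1039 UMIs, which held 8 and 5 of the Control nuclei. Cluster 6, led by Vip with a median of 5806 UMIs over all libraries, held 7 of them, against 34 and 15 in Control. Subclass shares and a few nuclei of high depth can therefore enter the folds above, which was not tested.

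The edgeR test called 0 of 9284 genes, with 955 at an unadjusted p under 0.05 (599 higher and 356 lower), and DESeq2 called 17 (12 higher, 5 lower). As lists, 17 of 18 glucocorticoid receptor target genes lay above 0 (9 higher adjusted over the list alone, among them Fkbp5, Zbtb16 at 3.10 and Nfkbia at 3.08; camera adjusted p = 2.67e-13), as did 13 of 13 mitochondrially encoded genes (9 higher; 3.62e-17), 14 of 14 heat shock genes (4 higher; 5.66e-07) and 16 of 17 immaturity genes (3 higher; 3.26e-04), each at adjusted p = 0.18 with an estimated correlation. Immediate early genes (16 of 18 above 0, 1 higher adjusted over the list alone; 5.05e-06), 8 cytokine genes (3 higher; 0.00630), 4 reactive glia genes (1 higher; 0.00691) and 10 interferon genes (1 higher; 0.0457) also passed camera, with adjusted p = 0.344, 0.18, 0.202 and 0.274 with an estimated correlation. Smooth muscle markers were higher beside them, with 8 of 8 above 0, a median of 3.41 (1.62e-20; adjusted p = 0.15 with an estimated correlation) and a sum of 1001 CPM against 267 and 230 CPM in Control. Glia markers summed to 218 CPM against 114 and 25.3 in Control, and macrophage markers to 36.3 CPM against 20.7 and 16.9. The mitochondrial list turned lower without the mitochondrial filter (adjusted p = 0.0279), and leaving out Stress 1, Stress 2 or Stress 3 gave 34, 16 or 9 changed genes.

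The lists that did not pass camera in Dexamethasone neuron-like nuclei were 14 neuropeptide genes (adjusted p = 0.210; Vip, Penk and Tac1 at 1.18 higher adjusted over the list alone), 8 nitrergic and VIP genes (0.614; Vip higher), 24 synaptic genes (0.325; 4 higher and Rims1 lower), 17 TGF-beta genes (0.539; Tgfb2 higher), 15 clock genes (0.539; Nr1d2 at 1.57 higher), 9 cholinergic genes (0.861), 5 mature glia genes (0.315), 26 axon guidance genes (0.0788), 6 corticosteroid receptor genes (0.660) and 4 sex-linked genes (0.606). Adjusted over the list alone, 0 genes passed in the last 5. The test recovered 7.60% of 2-fold and 53.4% of 4-fold changes in simulated counts of this comparison.

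The glial changes of stress and dexamethasone overlapped, in comparisons that share both Control libraries. In the fit of all 6 libraries, 93 genes were higher in both, 8 were lower in both and 0 went opposite ways, from 124 higher and 50 lower in Stress and 416 higher and 48 lower in Dexamethasone; Irgm1 and Arntl were among the shared ones. Across 7679 genes the log2 fold changes correlated at Pearson r = 0.634 with a covariance of 0.408, against a mean r of 0.473 and a covariance of 0.152 when unchanged groups were simulated against the same Control libraries. In neuron-like nuclei r was 0.565 and the covariance 0.290 over 9284 genes, against simulated values of 0.475 and 0.173. Genes are not independent replicates.

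In a test added after seeing the data, each treatment was set against a different Control library. With stress against Control 1 and dexamethasone against Control 2, r was 0.271 in glia-like nuclei, where 20 simulations of unchanged groups reached at most 0.0365. The other way round r was 0.308 (at most 0.0365 in simulations). Each Control group is 1 library in this fit, as is Dexamethasone, so all spread comes from the 3 Stress libraries. Calls of single genes in it are therefore not used. In neuron-like nuclei r was 0.137 and 0.176 (at most 0.0340 and 0.0241 in simulations). The glial covariance was 0.25 and 0.283 in these pairings, against 0.408 with both Control libraries shared, and the neuronal 0.116 and 0.165 against 0.290. In glia-like nuclei part of the agreement therefore came from the shared Control libraries and part remained without them. The simulations drew libraries around the same Control profile. Deviations of real libraries from their group means correlated at up to 0.191 in either direction in glia-like nuclei, and 0.128 in neuron-like nuclei. The simulated limits can therefore be too low, and they do not show that the remaining agreement came from the treatments. In neuron-like nuclei the excess was small, and without Control 2 it was not seen (r = 0.629, where simulations reached 0.642). A difference from Control in cluster shares or handling that both treatments have was not separated.

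The 2 treatments also differed in glia-like nuclei, in a comparison added after seeing the data: 231 genes differed between Dexamethasone and Stress by edgeR, 214 higher in Dexamethasone and 17 lower. Fkbp5 was higher in Dexamethasone than in Stress (1.71, adjusted p = 0.0173), as were Il6 (3.03, 2.64e-04), Nfkb1 (1.83), Mt2 (1.77) and Gfap (1.42, 0.00239), whereas Iigp1 (-2.30, 0.0300) and Nr3c1 (-1.52, 0.0362) were lower. Arntl stood at -0.02 (0.995). In neuron-like nuclei 5 genes differed, all higher in Dexamethasone: Eftud2, Atp12a, Mt1, Casp4 and Trp53inp1. The single Dexamethasone library is again assumed to vary like the others, and it had another Cell Ranger version. Cluster 10 held 82 of its 114 glia-like nuclei, against 34 of 124, 67 of 118 and 119 of 184 in Stress. Smooth muscle markers there summed to 741 CPM, against 190, 213 and 362 in Stress. Library, version and cluster shares were not separated from the treatment.

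The effect of stress differed between neuron-like and glia-like nuclei for 14 of 8199 genes in a model with the library as a block (665 at an unadjusted p under 0.05). Insig1 (log2 difference 2.09, neurons minus glia) and the immediate early gene Klf6 (1.85) had fallen in glia-like nuclei alone of the 2 classes tested, and the other 12, such as the ubiquitin ligase gene Arih1 (-2.58), the elongation factor gene Ell2 (-2.38) and the cell death kinase gene Ripk1 (-2.13), were higher in stress glia-like nuclei relative to neurons. Arih1 is also a leading gene of cluster 10, and within that cluster its stress change was 2.73, against 0.96 (adjusted p = 0.119) within cluster 9. With DESeq2 size factors Arih1 alone of the 14 remained, and leaving out libraries gave 22, 2, 1, 44 and 8 genes without Control 1, Control 2, Stress 1, Stress 2 and Stress 3.

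The neuron-like share of nuclei was 17.2% ± 4.86 (SD, n = 2) in Control and 12.5% ± 5.06 (SD, n = 3) in Stress, a difference of -4.67 points (exact permutation test, two-sided p = 0.6, adjusted p = 0.75 over 5 shares; the smallest p for 10 splits is 0.1). Of neurons and glia together, neurons were 37.4% ± 9.03 and 34.5% ± 12.3 (exact p = 1.0). Among neuron-like nuclei the excitatory-like share was 45.3% ± 4.81 in Control and 40.5% ± 1.85 in Stress (exact p = 0.2), the inhibitory-like share 48.1% ± 2.69 and 50.3% ± 3.75 (0.6), and the sensory-like share 6.56% ± 2.12 and 9.17% ± 3.08 (0.4). In the Dexamethasone library 19.0% of nuclei were neuron-like (exact binomial 95% interval 15.1% to 23.3%) and 58.6% of its neurons sensory-like (46.2% to 70.2%), intervals that cover counting error only. The sensory-like share was 21.1% with the stricter filter (4 of 19 neurons) and 40.0% without the mitochondrial filter. At clustering resolution 2.0 the rule also counted as sensory-like a cluster of 82 nuclei led by Penk, Tac1 and Syt4 (median 805.5 UMIs), with no sensory marker among its 10 leading genes. The sensory name of low-depth nuclei is therefore uncertain. The sort and the mitochondrial filter can set these shares: without that filter the neuron-like difference was 2.84 points in the other direction.

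In GRCm38 coordinates of the GENCODE M21 annotation, Irgm1 (ENSMUSG00000046879) chromosome 11 from 48861968 to 48871683, Iigp1 (ENSMUSG00000054072) chromosome 18 from 60376027 to 60392634, and Arntl (ENSMUSG00000055116) chromosome 7 from 113207465 to 113314126. Tef (ENSMUSG00000022389) spans chromosome 15 from 81802421 to 81826863, Atf3 (ENSMUSG00000026628) chromosome 1 from 191170296 to 191218039, Fkbp5 (ENSMUSG00000024222) chromosome 17 from 28399094 to 28517527, and Nr4a3 (ENSMUSG00000028341) chromosome 4 from 48045153 to 48086447. Tubb5 (ENSMUSG00000001525) spans chromosome 17 from 35833921 to 35838306, Tubb2a (ENSMUSG00000058672) chromosome 13 from 34074274 to 34078007, and Vip (ENSMUSG00000019772) chromosome 10 from 5639218 to 5647617. All are annotated as protein-coding. Counts are per gene, so exonic and intronic UMIs cannot be told apart, and closely related families such as the tubulins, the immunity-related GTPases and the metallothioneins are uncertain where reads could match more than 1 member.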

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

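Of the tests in this part, those of macrophage RNA, of glial clusters, of a shared difference of the libraries, of neuron subclasses and of other splits were chosen only after the result was seen. Those of depth, as summed totals, and of gene length were set before.

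By an interaction test, the difference of Stress from Control was unlike in neuron-like and glia-like nuclei for 14 genes. With DESeq2 size factors or without Stress 1, Arih1 alone of them kept its call. Shares of the glial clusters were not separated from these differences. Values are the log2 effect in neurons minus that in glia: Arih1 (-2.58), Ell2 (-2.38), Mapk4 (-3.39), Taf4b (-2.52), Eprs (-2.51), Aff1 (-1.90), Ripk1 (-2.13), Ythdc1 (-1.84), Cstf3 (-1.63), Nup210l (-3.77), Brinp1 (-1.81), Klf6 (1.85) and Insig1 (2.09). Dlgap2 had a fitted difference of -6.59 that rests on 0 UMIs in Control glia-like nuclei against 23 in Stress, at least 4.19-fold higher, and 381 against 900 in neuron-like nuclei.

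Genes also changed in classes outside the 2 that the report compares. In stress against control there were 4 in epithelium-like, 8 in smooth muscle-like and 25 in fibroblast-like nuclei; in dexamethasone against control there were 4, 9 and 65, and 6 in lymphatic endothelium-like nuclei. Of the smooth muscle-like nuclei, cluster 18 had no smooth muscle marker among its 10 leading genes and held 8 and 2 of the Control nuclei and 20, 11 and 32 of the Stress nuclei. Cluster 5 alone, an alternative added after seeing the data, gave 14 genes in stress and 21 in dexamethasone.

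Interferon genes were higher in stress glia-like nuclei. Macrophage markers there were at 28.9 CPM in Stress and 12.1 in Control, against 4529 in macrophage-like nuclei, which allows 0.638% of the RNA to come from macrophages where 84.8% would be needed for the rise; a first version of this test, on 4 of 23 immune markers (median 1.17, SE 1.13, against 1.62), decided nothing and was replaced. The list's median was 1.56 within cluster 9 and 1.57 within cluster 10, against 1.62 over all glia-like nuclei, with a largest camera adjusted p of 4.58e-09, which argues against the clusters' shares as the whole cause. With an estimated correlation the list passed in neither cluster (adjusted p = 0.151 and 0.394), and 1 of 8 and 4 of 10 tested members rose singly. After thinning to 310280 UMIs per library 6 of the 10 called genes were still called, so unequal summed totals did not make those 6 calls. Thinning the sums keeps each gene's share of them, so it cannot test depth per nucleus. The list was also higher in epithelium-like (median 1.78, camera adjusted p = 2.82e-09) and fibroblast-like nuclei (1.23, 0.0324), at adjusted p = 0.185 and 0.258 with an estimated correlation. The epithelium-like nuclei lay in different clusters by library: cluster 2 held 35 and 0 in Control and 26, 156 and 7 in Stress. In cluster 0 alone, added after seeing the data, too few interferon genes could be tested, so cluster shares stay open for that class. What stays open, untested, is a response to interferon not limited to glia and a difference between the libraries that the labels do not give. Depth per nucleus and RNA of lymphatic endothelium, whose markers were also higher, stay open too.

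Clock genes changed in stress glia-like nuclei. After thinning the sums to equal totals, edgeR still called 2 of the 3 genes: Arntl (-2.80, adjusted p = 0.00438) and Tef (1.93, 0.00581), with Per2 at 2.41 (0.0530). Unequal totals therefore did not make those 2 calls, but depth per nucleus was not tested. In 3 of the 3 classes outside the enteric nervous system where both were tested, Arntl was lower and Tef higher as well, but both passed only in fibroblast-like nuclei (adjusted p = 0.0494 and 0.00750). They were at 0.0660 and 0.0492 in smooth muscle-like and at 0.169 and 0.244 in epithelium-like nuclei. In smooth muscle-like cluster 5 alone Tef was higher (3.55, 0.00398) and Arntl was not tested. A shared difference of the libraries in time of collection, day or batch therefore cannot be told apart from a response of the animals to stress, since the labels give no time of collection.

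Neuronal immaturity genes were higher in stress neuron-like nuclei. Left-over cytoplasmic RNA would favour short genes: genes in the lowest quartile of length had a median of 0.25 and those in the highest -0.09, and the list's genes are short (median 5982 bp against 42320). Only 0.69% of 10000 lists matched on length and expression had a median as high (0.59, where the middle 95% of lists ended at 0.48), which argues against gene length as the whole cause. Malat1, a nuclear RNA, made up 10.0% and 11.6% of all UMIs in Control and 6.66%, 7.89% and 5.58% in Stress, and 5.01% and 7.29% against 5.73%, 4.25% and 4.22% in neuron-like nuclei. Left-over cytoplasm acting otherwise than through gene length was not tested and stays open. After thinning to equal totals, the list's camera adjusted p was 1.29e-08, so unequal summed totals did not make the call. Depth per nucleus was not tested and stays open. Different neuron subclasses in the groups cannot be told apart. The list's median was 0.59 in inhibitory-like nuclei (adjusted p = 4.12e-07; 0.153 with an estimated correlation) but 0.37 in excitatory-like nuclei with an adjusted p of 0.0681, which keeps this open. The list was also at adjusted p = 0.119 with an estimated correlation, so a change of neuronal maturity stays open, beside these, and was not tested apart from them.

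The 5 libraries make 10 splits into 2 and 3, too few for a share under 0.05: for stress glia-like nuclei the real split gave 137 genes and the highest other split 2, so 1 of 10 was as large.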

How the results depend on the processing

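In this part the settings without the mitochondrial filter, without Control 1 and Stress 1 and with a different Control library for each treatment were chosen only after the data were seen.

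Numbers of changed genes moved by over 1.5 times as follows; the cause was not tested. By the DESeq2 test there were 77 (stress, glia-like), 196 (dexamethasone, glia-like), 16 (stress, neuron-like) and 17 (dexamethasone, neuron-like), against 137, 464, 0 and 0 by edgeR. Thinning gave 83, 1 (stress, neuron-like) and 17 (dexamethasone, neuron-like), the stricter filter 32 (stress, glia-like), and no filter on low counts 157 and 212 in neuron-like nuclei. Without the mitochondrial filter there were 279 (stress, glia-like) and 95 (dexamethasone, neuron-like), and without Control 1 and Stress 1 254 and 75 in stress. Leaving out 1 library gave 35 to 174 (stress, glia-like), 308 to 476 (dexamethasone, glia-like), 0 to 1 (stress, neuron-like) and 0 to 34 (dexamethasone, neuron-like).

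Changed lists numbered 2 (stress, glia-like), 4 (stress, neuron-like), 6 (dexamethasone, glia-like) and 8 (dexamethasone, neuron-like) by camera, and 1, 0, 0 and 0 with an estimated correlation. In stress, fry's directional test gave 1 and 1 and its mixed test 7 in glia-like nuclei, and without the mitochondrial filter dexamethasone gave 10 in glia-like nuclei. In dexamethasone neuron-like nuclei fry's directional test kept the immaturity list alone of those called by camera. In dexamethasone glia-like nuclei it lost the neuropeptide list alone and gained the clock list. Leaving out 1 library gave 1 to 3 and 3 to 6 lists in stress. The difference between classes was called for 1 gene with DESeq2 size factors, 38 without a filter on low counts and 1 to 44 leaving out 1 Stress library, against 14. Of those 14 genes, 1 was kept with DESeq2 size factors and 14 without the filter. Leaving out Stress 1, Stress 2 and Stress 3 kept 1, 13 and 5 of them. With DESeq2 size factors and without Stress 1, the gene kept was Arih1.

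The correlation of the treatments was 0.714 to 0.748 (glia-like) and 0.629 to 0.813 (neuron-like) leaving out 1 Control library. Simulations of unchanged groups reached at most 0.719 (glia-like, r = 0.748) and 0.807 (neuron-like, 0.813) without Control 1, and 0.705 (0.714) and 0.642 (0.629) without Control 2, so the last lies within no change. With a different Control library for each treatment it was 0.271 and 0.308 (glia-like) and 0.137 and 0.176 (neuron-like). The neuron-like share difference turned to 2.84 points without the mitochondrial filter and ranged from -8.11 to -1.23 leaving out 1 library; it was -6.87 with the stricter filter.

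With replicate number as a block, stress gave 155 genes in glia-like and 25 in neuron-like nuclei and a share difference of -6.59. Only 2 pairs share a number, the labels give no shared batch, and deviations from the group means correlated between libraries of equal number at -0.17 and -0.01 (glia-like) and 0.09 and 0.13 (neuron-like), so the block is not used.

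Genes that turned direction had not passed in either setting. In stress these were, in glia-like nuclei, Nr3c1 (-0.018 thinned, -0.0087 without the mitochondrial filter) and Sox10 (-0.10 stricter filter, -0.32 without Control 1 and Stress 1, -0.18 without the mitochondrial filter), and in neuron-like nuclei Nr3c1 (-0.11 thinned), Fkbp5 (-0.023 DESeq2, -0.057 block), Chat (0.033 thinned, 0.31 stricter filter), Slc5a7 (-0.15 without Control 1 and Stress 1), Nos1 (-0.037 without the mitochondrial filter) and Tgfb2 (0.0052 no low-count filter, 0.018 doublets kept, 1.98 stricter filter, 1.30 without Control 1 and Stress 1). In dexamethasone they were Csf1 in glia-like nuclei (-0.12 without the mitochondrial filter), and in neuron-like nuclei Nr3c1 (0.070 without that filter) and Chat (-0.0088 DESeq2, -0.0042 no low-count filter, -0.24 thinned, -0.32 without the mitochondrial filter). Leaving out 1 library ranged, in stress glia-like nuclei, from -0.016 to 0.16 (Nr3c1), -0.30 to 0.92 (Nr4a1) and -0.00065 to 0.78 (Sox10), and in dexamethasone glia-like nuclei from -0.32 to 0.54 (Csf1), -0.57 to 0.66 (Nr4a1) and -0.61 to 0.11 (Sox10). In stress neuron-like nuclei it ranged from -0.076 to 0.58 (Nr3c1), -0.33 to 0.24 (Fkbp5), -0.43 to 0.060 (Chat), -0.0026 to 0.78 (Slc5a7) and -0.46 to 1.15 (Tgfb2), and in dexamethasone neuron-like nuclei from -0.24 to 0.25 (Chat) and -0.26 to 0.54 (Slc5a7).

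Over the named genes, 446 of 513 values (stress, glia-like), 290 of 333 (dexamethasone, glia-like), 219 of 269 (stress, neuron-like) and 118 of 175 (dexamethasone, neuron-like) kept direction and side of the threshold.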

Other observations

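In this part the tests of neighbouring genes, sterol genes and smooth muscle markers were chosen only after the result was seen.

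Outside the enteric nervous system, fibroblast-like nuclei showed an immediate early response in stress: 7 of 15 genes of that list rose (camera adjusted p = 6.59e-15; adjusted p = 0.145 with an estimated correlation), among them Egr1 (1.85 ± 0.33, adjusted p = 0.0132 by edgeR) and Fos (1.80, 0.0304). Nr4a3 had 1 UMI in Control and 95 in Stress (ratio 38.0, 95% counting interval 6.66 to 1516), and Tnfaip6, an inflammation-induced matrix gene, rose by 4.12 ± 0.62 (adjusted p = 0.00423). In epithelium-like nuclei the antiviral gene Oasl2 rose from 2 to 95 UMIs (17.9, 4.83 to 150; adjusted p = 0.0442), and the interferon list had a median of 1.78 (2.82e-09; adjusted p = 0.185 with an estimated correlation). Epithelium-like cluster 2 held 35 and 0 of the Control nuclei and 26, 156 and 7 of the Stress nuclei, so these 2 values can reflect cluster shares.

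In the Dexamethasone library the glucocorticoid target Fkbp5 rose in epithelium-like (2.91 ± 0.49, adjusted p = 0.0146 by edgeR), smooth muscle-like (3.41 ± 0.49, 0.00394; 3.32 in cluster 5 alone), fibroblast-like (3.58 ± 0.56, 6.68e-05) and lymphatic endothelium-like nuclei (3.37 ± 0.55, 0.00146), with the single library assumed to vary like the others. Its epithelium-like nuclei were 8, against 155 and 32 in Control, in other proportions of clusters. In fibroblast-like nuclei 7 of 15 glucocorticoid receptor target genes rose (4.94e-18; adjusted p = 0.0613 with an estimated correlation). Among inhibitory-like neurons taken alone, 10 genes changed in stress, 4 of them mitochondrially encoded, such as mt-Co3 (1.47, adjusted p = 0.0177), beside Tubb5 (1.86 ± 0.31, 0.0200). In dexamethasone, with 15 such nuclei against 73 and 31 in Control, 56 changed, 9 of them mitochondrially encoded, beside Fkbp5 (2.29, 0.0104). The list of 13 mitochondrially encoded genes had medians of 1.34 and 1.87 (5.88e-28 and 1.77e-32; adjusted p = 0.153 and 0.102 with an estimated correlation). In excitatory-like neurons 1 gene changed in stress, Tubb5 was at 0.87 (adjusted p = 0.763) and the mitochondrially encoded list had a median of 0.08. In dexamethasone, with 14 excitatory-like nuclei against 77 and 26 in Control, Fkbp5 was at 1.01, Tubb5 at -0.03 and mt-Co3 at -0.05. Nuclei were kept by their mitochondrially encoded share, so the filter bears on the mitochondrially encoded genes. Without it, that list over all neuron-like nuclei turned downward in both treatments, without passing in stress. The neuron subclasses were not tested without the filter.

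Sterol synthesis genes were lower in stress glia-like nuclei, a list chosen after seeing the data: Insig1 (-1.93), Msmo1 (-1.69), Fdft1 (-1.56) and Hmgcs1 (-1.48) fell, and all 11 tested members lay below 0. The 7 members not called had a median of -0.94, and 0% of random lists matched on expression had a median as low (the middle 95% of lists began at -0.42), so the pathway may be lower as a whole. The median was -0.31 over 16 genes in dexamethasone glia-like nuclei and -0.05 over 22 genes in stress neuron-like nuclei.

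Smooth muscle markers had a median of 3.41 in the Dexamethasone library's neuron-like nuclei and 3.64 in its glia-like nuclei, so RNA of smooth muscle cells in that library's droplets is a candidate source, although the sort was meant to remove those cells.

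Of 416 genes called higher in dexamethasone glia-like nuclei, 40 lay within 100 kb of another on the same strand, against a median of 19 over 2000 random lists, of which 0% had as many. On the opposite strand the count was 54 against 18. Transcription running on into a neighbour cannot be told apart from shared regulation, since both strands had an excess, a condition added after the same-strand count was seen.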
